A study of Mus musculus with 4 samples.

How the data were processed

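RNA was sequenced from cells of the dental pulp, the soft tissue inside the tooth, of XLacZ4 mice. XLacZ4 is a reporter line in which the bacterial enzyme beta-galactosidase (LacZ) is made in pericytes and vascular smooth muscle cells, the mural cells that wrap small vessels. Per the labels' protocols, teeth were dissociated to single cells, the cells were stained with FDG, a substrate that becomes fluorescent when beta-galactosidase cleaves it, and positive cells were collected by fluorescence-activated sorting. The labels give 4 libraries, 2 from molar pulp and 2 from incisor pulp. The protocol text of the incisor libraries also speaks of molars, and tissue was taken from the title, source and tissue labels, which all name the incisor. Nothing in the labels says whether the 2 libraries of a tissue came from separate animals, so the deposited q values speak only for these libraries. How those q values took up the spread between libraries, which may be technical, is not given.

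The data are a single table with 1 row per gene, in which the authors had already combined the libraries of each tissue. Per the file headers, the authors' table gives an FPKM value (fragments per kilobase of transcript and per sequencing depth) for the incisor and for the molar, a log2 fold change, a test statistic (a score that carries the sign of the fold), a p-value and a q-value. The submitters' processing notes name Trim Galore, HISAT2, edgeR and the mm10 build. The column layout is that of the gene table written by Cuffdiff, which no label names, and the tool that made the table, its library scaling, its annotation and the settings are not given in the sources used here. The authors' log2 fold change equals log2 of the molar over the incisor FPKM without a pseudocount, so a positive value means higher in molar, and a gene listed at 0 in a tissue has no finite fold. Conditions were tied to tissues by the description label of each library. Start positions were moved by 1 base so that all coordinates are 1-based on mm10. A row's interval can span a locus that it shares with other genes.

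The table had 24216 rows. The authors' status column marked 18770 as tested, 5444 as not tested, 1 as failed and 1 as holding too much data. A single value per tissue allows no SD, no n and no test of samples, so the count model planned for per-library counts was not fitted, and the comparison of the authors is described with their q values. Genes with q under 0.05 are named "called" below. The authors' own mark of significance reached up to q = 0.0600, and the smallest unmarked q was 0.0602. The smallest p in the deposited table was 5e-05, with q = 0.000664, shared by 1414 called rows, so q does not rank these genes further. Depth cannot be read from FPKM, and no interval that needs it is given.

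Gene lists were fixed before the data were examined, 35 in all, including markers of other cell types that the sort could hold. They cover pericytes, contractile smooth muscle, odontoblasts and osteoblasts, pulp fibroblasts, mesenchymal stem cells, tooth patterning transcription factors, proliferation, the Wnt, Hedgehog, BMP and TGF-beta, Notch and FGF pathways, collagens and matrix, angiogenic factors, axon guidance, endothelium, macrophages, osteoclasts, neutrophils, lymphoid cells, erythroid cells, dental epithelium, Schwann cells and glia, skeletal muscle, periodontal ligament, cartilage, dissociation stress, lysosomes, glycolysis and hypoxia, the interferon response, inflammation and chemokines, ion channels, mitochondrially encoded genes, ribosomal proteins and nuclear oxidative phosphorylation. Single-gene symbols numbered 23712 after the row with the highest mean FPKM was kept for each repeated symbol, which set aside 273 rows. Another 231 rows join several genes and were left out of lists. Of the list symbols, 7 were found under an older symbol through the RefSeq synonyms of GRCm38.p6, 5 lay in joined rows and 17 had no row, among them all 13 mitochondrially encoded genes.

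For each list the called genes were counted in each direction, over all genes tested and with p-values adjusted over the list alone by the Benjamini-Hochberg method. A list's median of log2((molar FPKM + 1) / (incisor FPKM + 1)) was taken over members with an FPKM of at least 1 in either tissue and placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. A list is said to lie apart when its percentile was under 2.5 or above 97.5. With a pseudocount of 1, this scale understates the difference of low genes, and the percentile describes these libraries without a p-value, since genes are not replicates. Transcript lengths and the share of 32-base words that a transcript shares with other genes came from GENCODE M21, using the longest transcript with a RefSeq mRNA where there was one. A length was found for 99.2% of the 13082 genes at 1 FPKM or more. In tests on simulated data with 13082 genes and 200 lists of 25 genes, 4.0% of lists without an effect fell outside the limits and 90.0% of lists moved by 1 on the log2 scale did. In a further test all genes carried a simulated length trend and lists without an effect were drawn from the shortest genes. Of these lists, 69.0% fell outside with expression matching and 3.5% with matching on expression and length. The simulated lists were drawn at random from genes with shuffled differences and simulated lengths, so their members did not vary together. Members of the lists used here may vary together, and these rates need not hold for them.

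Named genes followed a rule fixed before the data were examined. It takes the 10 called genes with the largest fold in each direction at an FPKM of at least 10 in the higher tissue, without predicted gene models and pseudogenes, up to 4 members with the smallest q per list with up to 3 per direction, and 15 genes in every case. The rule's demand that both libraries of a tissue exceed both of the other could not be applied. Genes listed at 0 could not be ranked by fold, which set aside 6 molar and 2 incisor genes from the top 10. Ties in q were ordered by the log2 difference. Other genes named below were chosen after their values were seen, and some genes that the rule selects are not reported here. Alternatives set before the data were examined were a stricter q threshold and a 2-fold minimum with pseudocounts. Chosen after seeing the data were FPKM minimums, the authors' own mark, other pseudocounts for the list medians, other scalings, matching on transcript length, and leaving out genes listed at 0, joined rows and genes that share sequence. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.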

Results

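FDG-positive cells of mouse molar pulp were compared with those of incisor pulp, 2 libraries per tissue, to find how the sorted cells of a tooth that stops growing differ from those of a tooth that grows throughout life. All FPKM values, fold changes and q values below are the authors' values from the authors' deposited table, which holds 1 value per tissue. They carry no replicate error here, and the depth of the libraries is unknown. Differences are reported as called only where the authors' q lies under 0.05. With 1 combined value per tissue, a difference in sorting, preparation or sequencing cannot be told apart from one between the teeth.

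Of 18770 tested genes, 3032 were called in the authors' deposited table, 2228 higher in molar (11.87%) and 804 higher in incisor (4.28%). Among these, 223 molar-higher genes were listed at 0 in incisor and 78 incisor-higher genes were listed at 0 in molar. The table gives no read counts, so a listed 0 does not show that a gene was absent. The lists that lay apart toward molar were endothelium, dissociation stress, inflammation and chemokines, ribosomal proteins, erythroid genes and cartilage. Toward incisor lay dental epithelium, proliferation, periodontal ligament and cementum, odontoblast and osteoblast, Wnt signalling, Hedgehog signalling, mesenchymal stem cell, axon guidance, angiogenic factors, and collagens and matrix. That makes 6 and 10 of the 32 lists with at least 5 scored genes. The molar FPKM values summed to 815089 and the incisor values to 539574, a log2 ratio of 0.60, and the median log2 fold of genes above 0 in both tissues was 0.21. Both shifts are smaller than the smallest absolute log2 fold of a called gene, 1.10, so neither can turn a called direction, and calls under another scaling were not tested. For the lists fixed before the data were examined, the count adjusted over the list alone was the same where no second count is given. Genes for olfactory, vomeronasal and taste receptors, a list chosen after the values were seen, reached a 99th percentile of 3.73 FPKM in molar against 0.125 in incisor. The molar-higher genes Myocd, Des, Kcnma1, Meis2, Tfap2b, Dhh, Dll1, Dll4, Cdh19, Il7r and Rhag, named below, had molar values within that range and are uncertain.

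**Figure D1:**
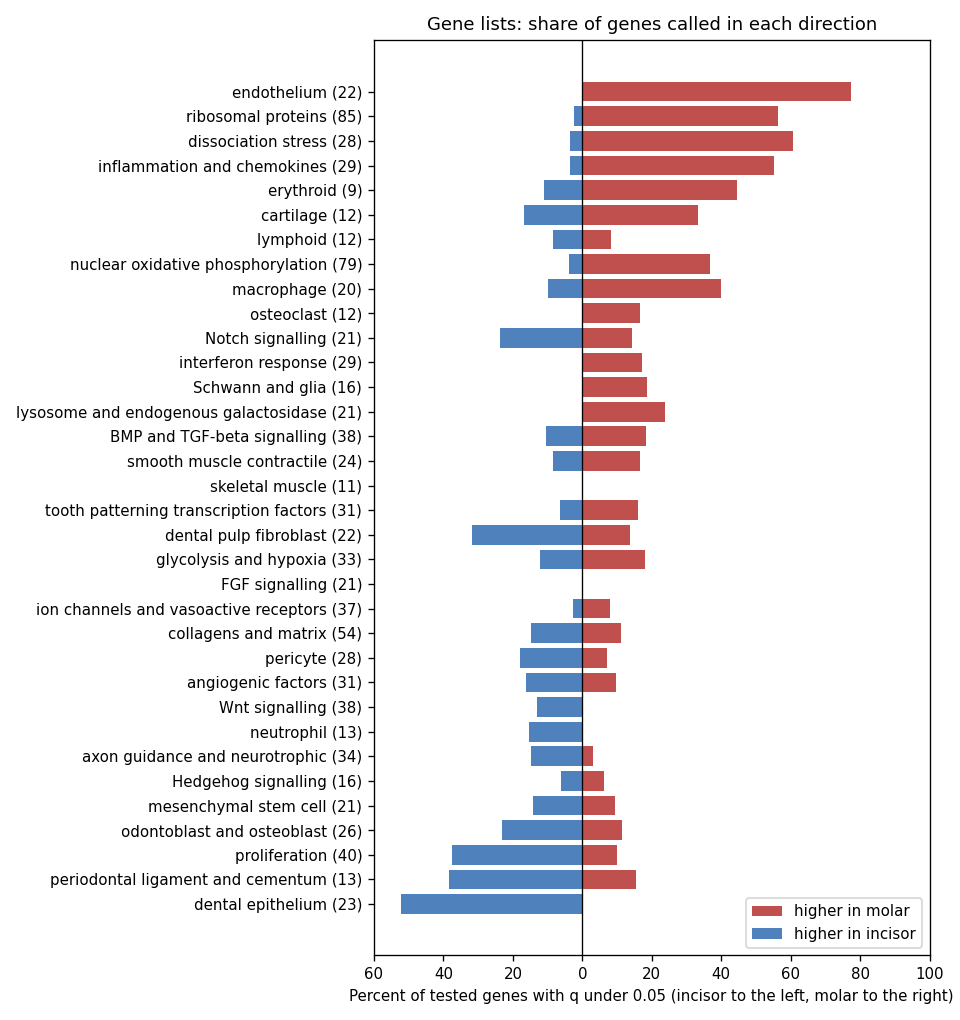
Percent of tested genes of each list with q under 0.05 in the authors' deposited table, higher in molar to the right and higher in incisor to the left, with the number of tested genes in brackets and lists ordered by median log2 difference. Endothelium (17 of 22 genes toward molar) and dental epithelium (12 of 23 toward incisor) form the ends of the plot.

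Mural cell genes went both ways, and the share of mural cells in each sorted fraction was not identified. Macrophage and dental epithelial genes were abundant too, with Lyz2 at 1903 in incisor and 3340 in molar and Amelx at 20642 and 1937. Whether the values below reflect that share or expression within mural cells was not tested. Rgs5, a regulator of G-protein signalling used as a pericyte marker (chromosome 1, 169655501 to 169695813), was 4.24-fold higher in incisor in the authors' deposited table, with an FPKM of 537 against 127 in molar and q = 0.000664. The receptor Pdgfrb, which draws pericytes to vessels (chromosome 18, 61045150 to 61085067), was 2.40-fold higher in incisor, at 30.3 against 12.6 with q = 0.0353. Cd248 (82.5 against 35.4), Rgs4 (13.1 against 1.97) and the Notch target Heyl (26.5 against 3.76) were also higher in incisor. Kcnj8, the pore of the vascular potassium channel that ATP closes (chromosome 6, 142564939 to 142571356), was 6.78-fold higher in molar, at 108 against 16.0 with q = 0.000664, and Ndufa4l2, another pericyte-enriched gene, reached 145 in molar against 4.35 in incisor. In all, 2 of 28 pericyte genes were called higher in molar and 5 higher in incisor in the authors' deposited table, and the list median of -0.34 lay at percentile 6.05. That median was -0.54 with median centring and -0.93 with equal FPKM totals. Several classical markers were not called. Incisor and molar FPKM were 3.01 and 2.86 for Cspg4, 7.15 and 5.48 for Mcam, 2.57 and 5.07 for Notch3, and 4.33 and 2.40 for Abcc9, the partner subunit of Kcnj8.

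Contractile smooth muscle genes were called in both directions, and the same limit on the share of mural cells applies. Tagln (153 against 12.4) and Myl9 (1183 against 453), both bound to the contractile actin apparatus, were higher in incisor, though Tagln shares 53.5% of its transcript sequence with other genes and its value is uncertain. Des, the intermediate filament of muscle, was higher in molar (3.17 against 0.155), as were Ramp1 and Smtn, and the coactivator Myocd stood at 1.22 in molar and was listed at 0 in incisor. Of 24 tested genes, 4 were called higher in molar and 2 higher in incisor in the authors' deposited table (4 and 3 adjusted over the list alone), and the list median of -0.03 lay at percentile 16.8. Acta2, smooth muscle actin, was not called, at 78.8 in incisor and 48.4 in molar with q = 0.247. Among ion channels and vasoactive receptors, 3 of 37 tested genes were higher in molar, including Kcnj8 and Kcnma1 (1.26 against 0.243), and the mechanosensitive channel Piezo2 (5.44 against 0.843) was higher in incisor. The other 33 genes of that list were not called, 34 adjusted over the list alone, and its median lay at percentile 11.9.

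**Figure D2:**
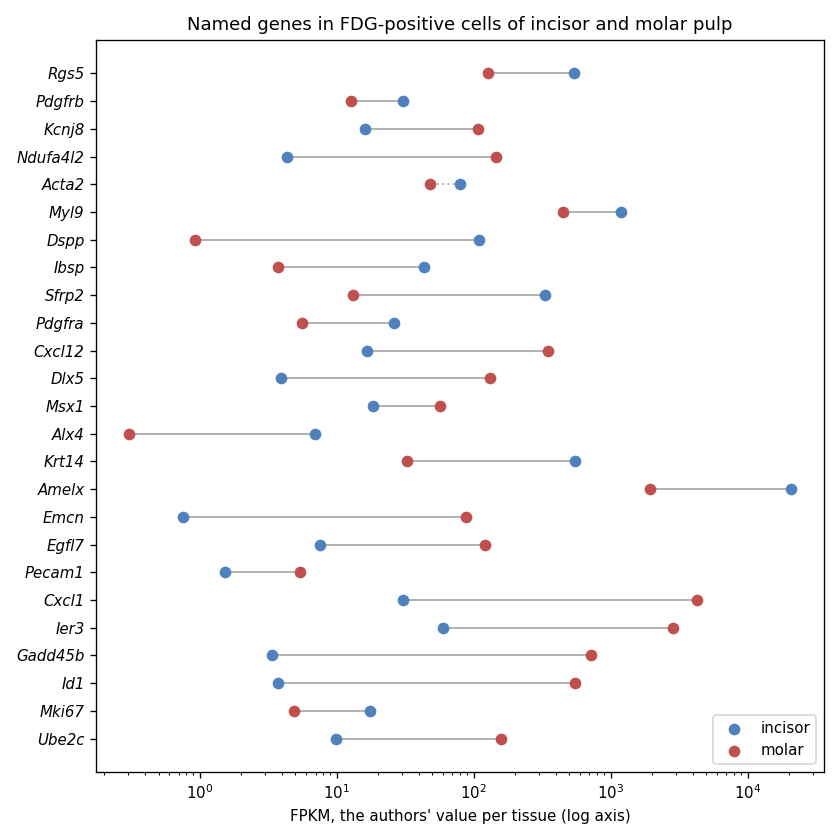
FPKM of 25 named genes in FDG-positive cells of incisor (blue) and molar (red) pulp on a log axis, 1 value per tissue from the authors' deposited table, with a dotted line for the gene that was not called. Rgs5 lies at 537 in incisor and 127 in molar, while Kcnj8 lies at 16.0 and 108.

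Among odontoblast and osteoblast genes more were called higher in incisor than in molar, and 17 of 26 were not called. Dspp, the precursor of dentin matrix proteins made by odontoblasts (chromosome 5, 104170703 to 104180127), was 118-fold higher in incisor, at 109 against 0.921 with q = 0.00375. That was the largest incisor-higher fold among the genes ranked in the authors' deposited table. The bone and dentin matrix gene Ibsp (43.0 against 3.71) and the pyrophosphate transporter Ank (18.9 against 3.32) were higher in incisor too. Alpl, the phosphatase of mineralisation, was higher in molar (183 against 61.1), as was the phosphate transporter Slc20a2. Of the 26 genes, 6 were called higher in incisor (7 adjusted over the list alone) and 3 higher in molar, and the median of -0.85 lay at percentile 0.02. Dental epithelial genes lay toward incisor too, and the cells behind this shift were not identified. The periodontal ligament and cementum list lay at percentile 0.07, with 5 of 13 genes higher in incisor, among them Tnn (20.7 against 0.860) and Postn (83.1 against 18.8), and 2 higher in molar, Fmod and Cthrc1. Cthrc1, a secreted protein of wound and bone matrix, stood at 412 in molar and 9.97 in incisor.

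Pulp fibroblast genes divided between the tissues. Sfrp2, a secreted binder of Wnt proteins (chromosome 3, 83766321 to 83774314), was 24.9-fold higher in incisor (330 against 13.2), and Smoc2 (52.9 against 11.1) and the growth factor receptor Pdgfra (26.4 against 5.55) were higher there as well. Cxcl12, a chemokine that holds stem and immune cells in their niche, was higher in molar (351 against 16.6), as were Apod (199 against 33.6) and Dcn. The counts were 7 of 22 higher in incisor (8 adjusted over the list alone) and 3 higher in molar in the authors' deposited table, at percentile 7.88, or below all random lists with a minimum of 5 FPKM. Of the mesenchymal stem cell list, 3 of 21 genes were higher in incisor (5 adjusted over the list alone), namely Pdgfra, Sox9 (31.2 against 10.6) and Itgav, while Cxcl12 and Eng were higher in molar. That list lay at percentile 0.37, but at 3.62 with a minimum of 5 FPKM. Gli1, a Hedgehog target that marks incisor stem cells, stood at 9.43 in incisor and 2.37 in molar and was not called (q = 0.206). Cartilage genes lay at percentile 98.3, or 92.7 with a minimum of 5 FPKM, with 4 of 12 higher in molar, including Col9a2 (33.5 against 8.45), and 2 higher in incisor, Sox9 and Hapln1.

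Of 31 tested transcription factors that pattern teeth and jaw, 24 were not called, 5 were called higher in molar and 2 higher in incisor, and the list median lay at percentile 25.2. Barx1, which is active in the molar region of the embryonic jaw (chromosome 13, 48663036 to 48666507), stood at 10.9 in molar and was listed at 0 in incisor, with q = 0.000664 in the authors' deposited table, and its absence from incisor is not shown by that value. Dlx5 (131 against 3.91), Msx1 (56.4 against 18.5), Meis2 (2.501 against 0.0319) and Tfap2b (1.09 in molar, listed at 0 in incisor) were higher in molar too, while Alx4 (6.91 against 0.306) and Sox9 were higher in incisor. Its relative Alx1 (18.9 in incisor and 0.150 in molar) was not called, with q = 0.322.

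Among signalling pathways, Wnt genes lay toward incisor at percentile 0.48, with 5 of 38 called higher in incisor (4 adjusted over the list alone) and none higher in molar in the authors' deposited table. These were Sfrp2, Sfrp1, the inhibitors Dkk2 (11.0 against 1.14) and Znrf3 (7.63 against 1.55), and the transcription factor Tcf7. The Hedgehog list lay at percentile 0.66, or 3.94 with a minimum of 5 FPKM, and only its receptor and target Ptch1 (13.6 against 2.59) was called higher in incisor, with the ligand Dhh higher in molar. Dental epithelial genes lay toward incisor as well, and the cells behind the Wnt and Hedgehog shifts were not identified. BMP and TGF-beta genes lay at percentile 28.8 with 7 of 38 higher in molar and 4 higher in incisor (8 and 5 adjusted over the list alone). Id1, a direct BMP target (chromosome 2, 152736251 to 152737410), was 148-fold higher in molar (548 against 3.70), and Id3 (5285 against 119) and the inhibitory Smad6 (9.61 against 0.482) were higher in molar too, while the activin subunit Inhba was higher in incisor (78.6 against 10.4). Notch genes lay at percentile 85.8, or 0.74 with a minimum of 5 FPKM, with Hey1 (41.1 against 9.14), Dll1 and Dll4 higher in molar and Notch2 (21.3 against 4.65), Heyl, Jag1, Dtx4 and Maml2 higher in incisor, 8 of 21 tested. Id1, Id3, Smad6, Hey1 and Dll4 are active in endothelial cells too, whose list lay toward molar, and the cells behind these values were not identified. None of the 21 FGF genes was called in the authors' deposited table, and their median lay at percentile 15.5.

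Markers of cell types outside the mural lineage differed between the tissues. Endothelial genes were called higher in molar in 17 of 22 cases (20 adjusted over the list alone) and higher in incisor in none in the authors' deposited table, with a median of 2.25 above all 10000 random lists. The size of that median depended on the setting, at 0.90 with a pseudocount of 5 and 3.71 with a minimum of 5 FPKM. Emcn, a sialomucin of capillary and venous endothelium (chromosome 3, 137341078 to 137431069), was 116-fold higher (87.6 against 0.756), Egfl7 stood at 120 against 7.49, and Cldn5 stood at 13.0 in molar and was listed at 0 in incisor, which does not show its absence there. Pecam1 was 3.53-fold higher in molar, at 5.40 against 1.53 with q = 0.0338. Dental epithelial genes went the other way, with 12 of 23 called higher in incisor (13 adjusted over the list alone), none higher in molar, and a median of -2.16 below all random lists. Amelx, the main enamel matrix protein, had the highest FPKM of any named gene in incisor, 20642, and still stood at 1937 in molar, a 10.7-fold difference. The basal keratins Krt14 (545 against 32.8) and Krt17 (267 against 19.8) and the epithelial protein Sfn (51.5 against 1.64) followed it.

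Blood and immune markers differed by cell type. Erythroid genes lay at percentile 98.5, or 92.9 with a pseudocount of 5, with 4 of 9 tested genes higher in molar, including Hbb-bt (157 against 3.20), Alas2 (40.9 against 2.59) and Rhag, and 1 higher in incisor (5 and 2 adjusted over the list alone). That gene, Car1, stood at 0.117 in incisor and was listed at 0 in molar, a value under the 0.125 of chemoreceptor genes in incisor and uncertain. The joined rows of the alpha-globin genes (1099 against 108) and of the beta-globin genes Hbb-b1 and Hbb-bs (1988 against 79.9) were higher in molar as well. Some macrophage genes were abundant in both tissues. Lyz2 stood at 1903 in incisor and 3340 in molar and C1qb at 1679 and 2145, neither of them called, while Fcer1g (800 against 166) and Spi1 (18.6 against 2.59) were higher in molar and Cx3cr1 (186 against 34.9) and Mpeg1 (49.0 against 4.67) higher in incisor. The macrophage counts were 8 of 20 higher in molar and 2 higher in incisor in the authors' deposited table, at percentile 52.8. Of the osteoclast genes, Acp5 (503 against 155) and Ocstamp were higher in molar, 2 of 12, at percentile 69.1. In the neutrophil list Camp (2.11) and Lcn2 (0.632) were called in incisor and listed at 0 in molar, 2 of 13, at percentile 6.28, or 0.93 when random lists were also matched on transcript length. Lymphoid genes were too low for a percentile, with Il7r higher in molar and Nkg7 higher in incisor out of 12 tested. Schwann and glial genes lay at percentile 52.8 with Cdh19, Fabp7 (56.9 against 21.02) and Cnp higher in molar out of 16 (3 and 1 adjusted over the list alone), and none of 11 skeletal muscle genes was called.

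Immediate-early and stress genes, which cells switch on within minutes of handling, were higher in molar in 17 of 28 cases (20 adjusted over the list alone), with a median of 1.94 at percentile 99.99. Ier3 stood at 2859 against 60.1, Gadd45b at 719 against 3.39 and Junb at 100.4 against 1.26, and the heat shock protein gene Hsph1 was the single one higher in incisor (46.1 against 16.3). Inflammatory genes and chemokines were higher in molar in 16 of 29 cases (17 adjusted over the list alone) in the authors' deposited table, with a median of 1.77 above all random lists. Cxcl1, a neutrophil attractant (chromosome 5, 90891245 to 90893115), was 141-fold higher (4283 against 30.4), Cxcl2 stood at 3949 against 78.6, Ccl2 at 6136 against 533, and the NF-kB inhibitor Nfkbia at 2418 against 32.8. Vcam1, an adhesion molecule, was the only gene of this list higher in incisor (126 against 36.4). Interferon response genes lay at percentile 64.6, with 5 of 29 higher in molar and none higher in incisor (7 and 2 adjusted over the list alone), led by the immunoproteasome subunit Psmb8 (177 against 8.85) with Bst2 and H2-K1.

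Among lysosomal genes, 5 of 21 were higher in molar, including Hexa (356 against 30.7), Gla (39.6 against 12.5), Ctsl and Neu1, and the list lay at percentile 19.1. Glb1, the endogenous beta-galactosidase that can also cleave FDG, shares a joined row with Tmppe that stood at 29.0 in molar and 13.4 in incisor and was not called (q = 0.124). Glycolysis and hypoxia genes divided, with Adm (27.9 against 1.92), Ddit4, Pgam1, Pgk1, Eno1 and Bnip3 higher in molar and Pkm (674 against 245), Pfkm, Hk2 and Ndrg1 higher in incisor out of 33 tested in the authors' deposited table (6 and 5 adjusted over the list alone), at percentile 5.75. Of these, Eno1, Bnip3, Pgk1, Pkm and Pgam1 share 42.1% to 76.95% of their transcript sequence with other genes and are uncertain, and Gapdh, with 84.0% shared, stood at 5.09 in incisor and 0.828 in molar and was not called.

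Proliferation genes were higher in incisor in 15 of 40 cases (16 adjusted over the list alone) and higher in molar in 4 in the authors' deposited table, and their median of -0.91 lay below all random lists. Dental epithelial genes lay toward incisor as well, and which of the sorted cells cycled was not identified. Mki67 (chromosome 7, 135689788 to 135716379), a marker of cycling cells, was 3.62-fold higher in incisor, at 17.5 against 4.84 with q = 0.00176, and the spindle protein Nusap1 (45.9 against 7.53) and the replication helicase subunits Mcm3, Mcm4, Mcm5 and Mcm7 were higher there too. Ube2c (159 against 9.92), Cenpa (69.8 against 6.58), Ccnb2 (74.0 against 13.0) and Plk1 were higher in molar. The transcripts of Ube2c, Cenpa, Ccnb2 and Plk1 span 967, 1466, 1531 and 2199 bases against 10061 for Mki67. These lengths bear on the length trend given below. With the median of each length bin taken away, the log2 differences of Ube2c, Cenpa, Ccnb2 and Mki67 were 2.76, 2.33, 1.54 and -1.37, so their directions held.

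Collagens and matrix genes lay at percentile 2.03, with 8 of 54 higher in incisor, including Thbs2 (37.9 against 1.94) and Col8a1 (12.5 against 2.17), and 6 higher in molar, including Col16a1 (10.9 against 1.48). When random lists were also matched on transcript length the percentile was 55.8. Angiogenic factors lay at percentile 1.91, or 7.64 with length matching, with Pdgfd (97.1 against 16.6), Thbs2, Angpt1, Angpt2 and Igf1 higher in incisor and Adm, Cxcl12 and Igf2 higher in molar out of 31. Axon guidance genes lay at percentile 0.51, with Epha3 (27.7 against 1.60), Epha7 (13.1 against 1.10), Efna5 (44.2 against 4.03), Slit3 and Robo1 higher in incisor and Sema3b (9.26 against 0.646) higher in molar out of 34 tested in the authors' deposited table (5 and 2 adjusted over the list alone). With a minimum of 5 FPKM the angiogenic and axon guidance lists moved to percentiles 68.6 and 65.2.

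The largest ranked folds toward molar belonged mostly to genes of general cell function. They were the ribosomal protein genes Rps13 (1760 against 1.05), Rps23, Rps27 and Rpl27, the ATP synthase subunit Atp5g2 (676 against 0.916), Ppia, Timm23, Tpt1, Nfkbib and the transcription factor Osr2 (103 against 0.361). Toward incisor, besides Dspp, Sfn and Sfrp2, stood the collagenase Mmp13 (375 against 4.37), the peptide precursor Nts (212 against 3.58), Dpep1 (149 against 4.12), Ckmt1 (125 against 3.50), Acpp, Aldoart1 and Rpl21 (79.3 against 1.10). Ribosomal protein genes were higher in molar in 48 of 85 cases and higher in incisor in 2 (55 and 3 adjusted over the list alone) in the authors' deposited table, with a median of 2.07 above all random lists, or 1.05 when centred in transcript length bins. Their log2 differences spread from -5.48 to 9.98, and abundant members such as Rps14 (6458 in incisor and 8146 in molar) were not called. They share a median of 58.2% of their transcript sequence with other genes, against 0.50% over all scored genes, so their values are uncertain. Among the other top genes Timm23, Atp5g2, Ppia and Tpt1 share 92.6%, 87.7%, 57.2% and 42.9%, so their values are uncertain too, as are those of Igf2 (76.0%), Hbb-bt (59.4%) and Mcm7 (46.8%). Nuclear oxidative phosphorylation genes were higher in molar in 29 of 79 cases and higher in incisor in 3 (35 and 3 adjusted over the list alone), for example Cox6a1 (1828 against 24.6) and Ndufa6 (817 against 8.21), with Sdha (139 against 47.5) the other way, at percentile 91.8, or 68.6 with length matching. Their median of 0.89 fell to 0.11 when centred in transcript length bins.

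Differences followed transcript length across the table. When genes were ranked by transcript length and cut into 5 equal groups, in the shortest group (up to 1573 bases) 29.3% were called higher in molar and 1.35% higher in incisor, and in the longest (from 4733 bases) 6.78% and 7.86%. Across genes, which are not independent replicates, Spearman's rho of log2 difference with length was -0.37. Ribosomal protein and oxidative phosphorylation transcripts are short, with medians of 833 and 760.5 bases. When random lists were matched on length as well, the collagen and angiogenic lists no longer lay apart and the neutrophil list did, and all other lists fixed before the data were examined kept their side. After the median of each length bin was taken away, 3 called genes changed direction.

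**Figure D3:**
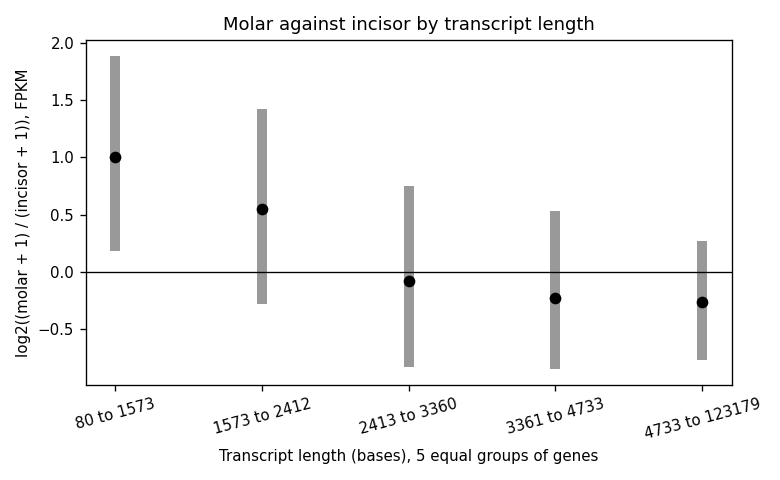
Median (points) and quartile range (bars) of log2((molar + 1) / (incisor + 1)) from the authors' FPKM for genes in 5 equal groups of transcript length, over 12983 genes at 1 FPKM or more in either tissue. The median runs from 1.01 in the shortest group to -0.27 in the longest.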

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

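The stricter q threshold and the 2-fold minimum with pseudocounts of 0.5, 1 and 5 were set before the data were examined, and all other alternatives run were chosen after seeing the data. No paired analysis was possible because the table holds 1 value per tissue and no replicate numbers. For the same reason the DESeq2 and voom fits, other count normalizations, the library totals without abundant gene classes, filters on library counts, the replicate block, leaving out each library, the estimated correlation and fry were not run. The count of molar-higher genes stayed between 1511 and 2376 under every alternative run. The incisor-higher count fell from 804 to 426 at q under 0.01, a stricter threshold by construction, and otherwise stayed between 621 and 880. Lists apart toward molar numbered 4 to 6 and toward incisor 8 to 10. Endothelium, dissociation stress, chemokines, ribosomal proteins, dental epithelium, proliferation, odontoblast, periodontal ligament and Wnt lists lay apart under all settings run. Among lists that lay apart, the median of collagens and matrix turned to 0.0104 when centred in transcript length bins, and with a minimum of 5 FPKM the medians of angiogenic factors and axon guidance turned to 0.36 and 0.23; the cause was not tested. Among lists that did not lie apart, 7 medians changed sign under at least 1 setting, 6 of them under equal FPKM totals, and the Notch median went from 0.37 to -1.20 with a minimum of 5 FPKM. Of the 118 called named genes with a fold, none with a length-centred value changed direction under length centring. Il7r, under 1 FPKM in both tissues, had no such value. The rule picked most of these genes for a large fold or a small q, so few could turn. Without per-library values and depth, no call can be checked against the spread between libraries.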

Other observations

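All tests in this part were chosen after the values had been seen. Genes of cholesterol synthesis, a list added later, lay toward incisor at percentile 0.06 and at 0.05 with length matching. Hmgcs1, an early enzyme of the pathway, stood at 44.7 in incisor and 3.19 in molar, and in all 4 of 20 genes were called higher in incisor and 1 higher in molar in the authors' deposited table, with the same counts adjusted over the list alone. Mast cell genes, also added later, lay below all random lists, with 4 of 12 tested genes called higher in incisor and 1 higher in molar (6 and 1 adjusted over the list alone). Cpa3 (2.12) was called in incisor and listed at 0 in molar, as were Tpsab1 (14.8), Mcpt1 (0.336) and Cma2 (1.06), which shares 58.6% of its sequence with other genes and is uncertain, while Tpsb2 (46.3 in incisor and 0.0958 in molar) and Cma1 (29.7 and 0.0578) were not called over all genes. The gene higher in molar was Mrgprb1 (1.34 in molar and listed at 0 in incisor), a molar value within the range of the chemoreceptor genes below. Histone genes, added later too, lay toward molar at percentile 99.81 but at 88.85 with length matching, with 2 of 38 tested genes called higher in molar and 1 higher in incisor, the same adjusted over the list alone.

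Ribosomal protein genes were higher in molar, and some processed copies of housekeeping genes had high values in incisor. Gm1821, a processed copy of a ubiquitin gene, stood at 6380 in incisor and 899 in molar. The ubiquitin gene Ubb, listed at 0 in incisor and 4509 in molar, is the row marked as holding too much data. Its 0 does not show absence, so Gm1821 cannot be compared with it. Rpl14-ps1 stood at 6186 and 1227, beside 3353 and 2639 for its parent Rpl14, which was not called. Of 30 pseudogene rows at 1 FPKM or more, 1 was called higher in incisor and 5 higher in molar. Transcript length as the whole cause is argued against, since the ribosomal list stayed at percentile 100 among lists matched on expression and length. Its median fell from 2.07 to 1.05 when centred in transcript length bins, so a part from length stays open. Reads shared with retrocopies may contribute. Across the 83 scored ribosomal protein genes, not independent replicates, Spearman's rho of log2 difference was 0.32 with shared sequence and -0.08 with length. The third of these genes with least shared sequence had a median of 1.22, with a 95% bootstrap interval across genes of 0.08 to 2.52. These values decide neither way. Genes of that group still share up to 46.1% of their sequence, so they are not free of such reads. Of 19 pseudogene and parent pairs, the pseudogene lay below its parent in 73.7%. Some pairs share a parent, and with 1 value per parent the copies lay below in 11 of 16 cases (exact sign test, two-sided, p = 0.21), with 2 parents under 1 FPKM in both tissues. Placing of parent reads on pseudogenes in incisor stays open, as does the difference between tissues, which was not tested.

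Endothelial genes were higher in molar and dental epithelial genes higher in incisor, in cells gated on FDG cleavage. A lower share of mural cells in the molar fraction would raise both only if the mix of the other cells stayed the same. Their medians differed by 4.41 on the log2 scale, at 2.25 (95% bootstrap interval across genes 1.34 to 2.60) and -2.16 (-2.63 to -1.80). These values argue against that case, while a lower mural share with a changed mix of other cells stays open. Transcript length as the whole cause is argued against for both gene lists, with percentiles of 100 and 0 under length matching. More endothelial cells in the molar fraction, and more epithelial cells or their RNA in the incisor fraction, stay open. That 100% of 21 scored endothelial genes were above 0 and 82.6% of 23 epithelial genes below 0 restates the pattern and decides nothing. Their most abundant members were Egfl7 (120 in molar) and Amelx (20642 in incisor). No endothelial gene and 1 epithelial gene is held by another list, 5 and 16 stood at 1 FPKM or more in both tissues, and whether the tissue or its dissociation would bring such cells was not tested.

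Stress and chemokine genes were higher in molar together. Length matching left both lists at percentile 100, which argues against transcript length as the whole cause. More macrophages in the molar fraction would raise macrophage, stress and chemokine genes alike only if macrophages were the main source of all of them. That source was not identified. The median of the 55 stress and chemokine genes exceeded the macrophage median by 1.27 (95% bootstrap interval across genes 0.11 to 2.08). That interval treats genes as independent, which they are not, so it does not decide whether macrophages are the whole cause. Of 20 macrophage genes, 8 were called higher in molar and 2 higher in incisor, but their median of 0.64 lay at percentile 52.8, so the list did not lie apart. More macrophages in molar were thus not shown, and they stay open as a part or the whole of the cause. A response to dissociation and a difference between the tissues in life, or in the state of macrophages, may each remain and were not tested.

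Genes for olfactory, vomeronasal and taste receptors, 1444 rows, were listed above 0 in 49 cases in incisor and 1199 in molar, with a molar median of 0.114 FPKM and a 99th percentile of 3.73. Of 715 tested, 19 were called higher in molar and 2 higher in incisor (18 and 2 adjusted over the list alone). The 91 scored genes had a median of 1.45, at percentile 100 with and without length matching. A list mostly at 0 in incisor thus lay apart toward molar too. Of 21 scored endothelial genes, 5 stood at 1 FPKM or more in both tissues, so the percentile of that list carries the same limit. Over all rows, 16625 were above 0 in incisor and 21011 in molar, and 161 called genes lay under 1 FPKM in both tissues. Both the X-inactivation transcript Xist (5.93 in incisor and 3.54 in molar) and the Y-linked gene Eif2s3y (16.4 and 9.55) were present in both tissues and not called.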
